A study of Mus musculus with 9 samples.

How the data were processed

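The samples were olfactory bulbs of 9 adult C57/BL6 mice, aged 6 to 8 weeks or older, in 3 groups of 3 separate mice. Clean air mice breathed air passed through activated carbon. Mice of the 30 min group were taken at the end of 30 min of exposure to a mixture of odorants. Mice of the 120 min group had 30 min of the odorants and then 90 min of clean air. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I, cleaned on a column, selected with oligo-dT beads and sequenced from paired ends.

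Per the submitters' processing notes, reads were aligned with Bowtie to the mouse genome build mm9. The Bowtie version, the annotation, the counting rule, the handling of reads with several matches and the use of strand are not given in the sources used here. The deposited table holds RPKM (read counts scaled by gene length and by library size), as made by the authors, for 27497 Ensembl gene identifiers in 9 columns with 2 decimals. Columns were matched to mice through the codes in the sample descriptions, and mouse numbers 1 to 3 are those of the sample titles. Of the identifiers, 7969 had a value of 0 in all 9 libraries. Values were used as deposited, without further scaling.

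Gene names came from the table for 20168 identifiers and from GENCODE release M21, by identifier, for 3642 more, and 3687 stayed unnamed. GENCODE M21 describes a later genome build than mm9, so it supplied names, gene spans, transcript sequences and 3′ UTRs by identifier and no positions are given. It held 22500 of the 27497 identifiers and 12132 of the 12780 tested. Older symbols of the table are kept: Bhlhb2 is Bhlhe40, Snf1lk is Sik1, Ccrn4l is the nocturnin gene, Gtl2 is Meg3, D12Ertd647e is Ifi27, Penk1 is Penk and DQ539915 is mt-Co1.

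The depth of each library was recovered from the spacing of the RPKM values of 1800 annotated RNAs under 200 nt, whose values are multiples of the value of 1 counted read. A length 34 nt shorter than annotated made 90.2% of the multiples whole within 0.05, against 32.6% with the full length, and 85.2% to 93.5% in single libraries. On simulated data, made with the same length 34 nt shorter, the largest error of the recovered depth was 0.0679%. That covers recovery under the assumed counting and does not test whether the libraries were counted so. Whether 1 counted unit was a read or a read pair is not given in the sources used here. The floor of each library was taken as 3 counts. Intervals and floors cover counting error only.

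Genes with a mean of at least 1 RPKM over the 9 libraries (12780) were tested on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). A single fit to all 9 libraries shared its spread over the 3 groups, with 6 residual degrees of freedom and a median of 10.7 after moderation. Contrasts were 30 min minus clean air, 120 min minus clean air, 120 min minus 30 min and the mean of both exposed groups minus clean air, and a moderated F test covered the 3 groups. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors of log2 changes are standard errors of the fit, and errors of RPKM means are standard deviations over 3 mice. The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. On simulated data with 50 genes per size of change, 50% to 56% of genes changed by 1 on the log2 scale were called, and 92% to 100% of those changed by 2 or more in either direction. Of the unchanged simulated genes, 0.0318% to 0.0556% were called. The genes of all sizes of change were altered together, with independent noise and without deviations shared by mouse number. These are more genes than the 10 to 18 called when 2 groups of the data were compared, which loosens the adjusted threshold. The shares called may therefore be too high for these data.

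There were 26 gene lists with 307 members, of which 287 were found and 258 tested. They covered immediate-early transcription factors, activity-regulated effector genes, feedback regulators of MAP kinase signalling, neuropeptides and secreted neuronal proteins, and glucocorticoid-responsive, circadian clock, heat shock and chaperone, interferon-stimulated, and synaptic vesicle and postsynaptic genes. Marker lists covered mitral and tufted cells, granule and other GABAergic interneurons, dopaminergic periglomerular cells, migrating neuroblasts, olfactory sensory neurons, olfactory ensheathing cells, astrocytes, oligodendrocytes, microglia, endothelial and mural cells, red blood cells, choroid plexus and meninges, and frontal cortex excitatory neurons. The last lists held nuclear-retained RNAs, mitochondrial genome genes, housekeeping genes and sex-chromosome genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists with at least 3 tested members, and beside it with an estimated correlation and with fry. Camera compares a list with all other genes. Fry's directional test asks whether the genes of a list move, on balance, in 1 direction, its mixed test whether they change in either direction, and neither compares the list with other genes. Nuclear-retained RNAs had 1 tested member, Gtl2. Several genes stand on more than 1 list, such as Per1, Bhlhb2, Vgf, Bdnf, Npy and Errfi1. Members without a match, among them Jun, Egr2, Scg2, Gpr3, Spry1, Camk2a, Malat1, Neat1 and Xist, were not analysed here.

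Genes were named by a rule. In each comparison it took called genes whose groups did not overlap, up to 15 with the largest rise and 10 with the largest fall. It also took up to 4 called members of each list, or where none was called up to 2 members with the highest mean RPKM, and a fixed panel of Fos, Egr1, Arc, Npas4, Nr4a1, Junb and Bdnf. Genes named outside it were chosen after their values were seen and are introduced as such.

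Mice of different groups share the numbers 1 to 3 in the labels, which do not say that a number marks a litter, batch or day. These are the numbers of the titles. The codes of the descriptions give mice 1, 2 and 3 of clean air the numbers 1, 2 and 5, and those of both exposed groups 1, 3 and 4, so that only mouse 1 has the same number in all 3 groups there, and the pairing with clean air rests on the correlations alone. The correlation, across genes, of the deviations of same-numbered libraries from their group means was at least 0.147 in each of the 3 pairs of the 30 min and clean air groups. By the criterion of more than 0.1 in every pair, numbers were treated as pairing there. The main fit nevertheless has no block, and a fit with the number as a block is reported beside it where it changes a call. The other comparisons had a pair under 0.1, although both exposed groups carry the same codes.

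Alternatives were pseudocounts of 0.1 and 1, no filter on low values, a mean of at least 3 RPKM, median ratio scaling, quantile normalization, a robust variance model, only the 2 groups compared, a 2-fold minimum, a threshold of 0.1, the block, and each library left out in turn. Array weights, voom weights from estimated reads, depth as a covariate and the leaving out of genes without a symbol in the table were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.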

Results

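Gene expression was measured by sequencing of polyadenylated RNA from the olfactory bulb, the brain region that receives the axons of the olfactory sensory neurons. The series set 3 mice kept in clean air beside 3 mice taken at the end of 30 min of odor and 3 mice taken at 120 min, after 30 min of odor and 90 min of clean air. Its title and design pose the question of which transcripts respond, and how fast, when neurons are active in the living animal. The depth recovered from the deposited RPKM was 10.5, 22.2 and 29.9 megareads (M) in clean air mice 1, 2 and 3. It was 8.82, 28.8 and 17.4 M in the 30 min mice, and 9.85, 24.1 and 7.15 M in the 120 min mice. For a transcript of 1 kb, 3 counts corresponded to 0.104 to 0.434 RPKM. In each library 12511 to 12815 genes reached 1 RPKM. Pearson correlations of log2 values, taken across genes that are not independent replicates, were 0.94 to 0.969 within groups and 0.932 to 0.977 over all pairs of libraries.

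After 30 min of odor, 17 genes were higher than in clean air, and 13 of them were on the list of immediate-early transcription factors, genes that neurons transcribe without prior protein synthesis when they are active. Fos, a subunit of the AP-1 transcription factor, rose 23.1-fold, from 6.96 ± 4.47 RPKM in clean air to 155 RPKM, with 170.8, 131.39 and 163.68 RPKM in the 30 min mice (errors of RPKM are SD, n = 3 mice per group; folds are from the fit of log2(RPKM + 0.5), not ratios of the mean RPKM). Arc, whose protein acts at synapses, rose 11.9-fold to 285 ± 46.0 RPKM from 25.4 ± 13.0 RPKM, and Fosb, a relative of Fos, rose 11.1-fold to 54.1 ± 1.60 RPKM. Npas4, a transcription factor induced by neuronal activity, rose 8.25-fold from 7.01 ± 1.40 to 60.9 ± 6.42 RPKM. The identifiers of the fixed panel were ENSMUSG00000021250 (Fos), ENSMUSG00000038418 (Egr1), ENSMUSG00000022602 (Arc), ENSMUSG00000045903 (Npas4), ENSMUSG00000023034 (Nr4a1), ENSMUSG00000052837 (Junb) and ENSMUSG00000048482 (Bdnf). The 1 gene that was lower was AK036329 (ENSMUSG00000053861), with 5.54 ± 0.23 RPKM against 13.0 ± 1.59 RPKM in clean air.

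Of 28 tested immediate-early transcription factors, 13 rose genome-wide and none fell. The zinc finger genes Egr1, Egr4 and Egr3 rose by 3.25 ± 0.35, 3.07 ± 0.26 and 1.70 ± 0.24 on the log2 scale (estimate ± SE). The orphan nuclear receptor genes Nr4a1, Nr4a3 and Nr4a2 rose by 2.99 ± 0.41, 1.87 ± 0.22 and 1.59 ± 0.18, of which Nr4a2 was named after its value was seen. Btg2, an antiproliferative factor, rose by 2.72 ± 0.17, Junb, a second AP-1 subunit, by 2.68 ± 0.22, Atf3, a stress-responsive factor, by 2.52 ± 0.22, and Ier2 by 2.23 ± 0.28. In RPKM, Egr1 went from 37.0 ± 26.4 to 307 ± 12.9, Nr4a1 from 38.9 ± 31.9 to 255.9 ± 19.7, Junb from 32.6 ± 9.21 to 207 ± 30.7 and Atf3 from 0.937 ± 0.150 to 7.83 ± 1.61. Adjusted over the list alone, 21 members passed, with Fosl2 (1.51), Klf2 (1.04), Klf4 (0.88), Klf10 (0.82), Nfil3 (0.79), Per1 (0.78), Bhlhb2 (0.67) and Srf (0.49) added, all of them named after their values were seen. The list's median log2 change was 1.27, and it rose against all other genes (camera adjusted p = 6.13e-43, adjusted p = 0.00299 with an estimated correlation).

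Of 25 tested activity-regulated effector genes, 2 rose genome-wide, Arc and Cyr61, the gene of a secreted matrix-associated protein. Cyr61 had a log2 change of 2.35 ± 0.37, with 24.32, 7.1 and 15.26 RPKM in the 30 min mice against a mean of 2.32 ± 0.30 RPKM in clean air. Adjusted over the list alone 7 passed, the others being the kinase genes Snf1lk (1.05) and Plk2 (0.94), Gadd45b (0.89), Tiparp (0.82) and Fbxo33 (0.53), named after their values were seen. The list rose with a median of 0.37 (adjusted p = 5.93e-06, adjusted p = 0.0182 with an estimated correlation, and adjusted p = 0.102 with an estimated correlation in the fit with the mouse number as a block). Bdnf, a neurotrophin gene of the same list, had 0.957 ± 0.287 RPKM in clean air and 1.23 ± 0.254 RPKM at 30 min, and its log2 difference of 0.26 ± 0.28 did not pass (adjusted p = 0.883). Of 12 feedback regulators of MAP kinase signalling, the phosphatase genes Dusp1 and Dusp6 rose by 1.97 ± 0.18 and 1.12 ± 0.16, to 56.6 ± 7.49 and 21.4 ± 0.49 RPKM. Adjusted over the list alone 5 passed, with Dusp14 (1.14), Dusp5 (0.95) and Spry4 (0.58) added after their values were seen. This list rose with a median of 0.30 (adjusted p = 5.93e-06, but adjusted p = 0.0686 with an estimated correlation).

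**Figure D1:**
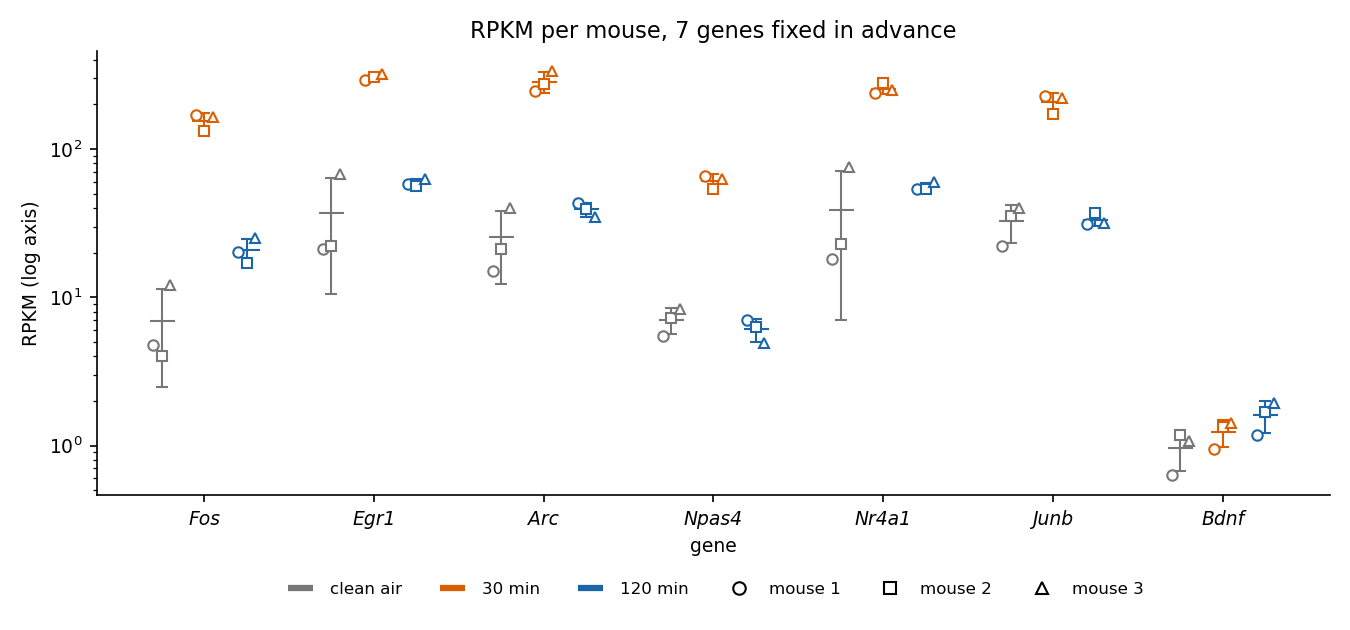
RPKM (log axis) of the fixed panel of 7 genes in each of the 9 mice, by group, with points for mice, horizontal lines for group means and error bars of 1 SD. Fos, Egr1, Arc, Npas4, Nr4a1 and Junb were highest in the 30 min mice, while Bdnf stayed between means of 0.957 and 1.60 RPKM.

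Markers of other cell types were tested beside these groups. Astrocyte markers rose as a list at 30 min, with a median of 0.26 (adjusted p = 0.0234, but adjusted p = 0.665 with an estimated correlation). Of the 8 tested none was called genome-wide and 1, the water channel gene Aqp4 (0.79, named after its value was seen), passed when adjusted over the list alone, while Aldoc and Gfap had 0.24 ± 0.23 and -0.02 ± 0.20. The 3 red blood cell markers rose as a list with a median of 1.05 (adjusted p = 0.0118, but adjusted p = 0.553 with an estimated correlation). None of the 3 was called, and the globin gene Hbb-b1, which has near-identical copies, had 171 ± 22.5 RPKM at 30 min and 85.0 ± 52.9 RPKM in clean air. In the fit with the mouse number as a block, heat shock and chaperone genes (median 0.25, adjusted p = 0.0998 without the block) and granule and other GABAergic interneuron markers (0.21, 0.147) also passed at adjusted p = 0.0479 each, but with adjusted p = 0.719 with an estimated correlation. No member of either was called, and Hspa8, Hsp90ab1, Gad1 and Synpr had 0.64 ± 0.26, 0.33 ± 0.18, 0.27 ± 0.21 and 0.16 ± 0.19.

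The other 18 lists did not pass at 30 min and held no called gene. Their medians with adjusted p were 0.23 (0.0998) for glucocorticoid-responsive genes, 0.36 (0.147) for endothelial and mural cells, 0.28 (0.171) for interferon-stimulated genes and -0.03 (0.235) for oligodendrocytes. They were 0.24 (0.293) for olfactory sensory neurons, 0.10 (0.293) for circadian clock genes, 0.11 (0.293) for synaptic genes and -0.06 (0.293) for olfactory ensheathing cells. Housekeeping genes had 0.27 (0.302), choroid plexus and meninges 0.21 (0.327), sex-chromosome genes -0.11 (0.373), mitochondrial genome genes 0.40 (0.427) and mitral and tufted cells 0.16 (0.522). Frontal cortex neurons had -0.05 (0.593), microglia 0.06 (0.864), neuropeptides 0.02 (0.956), dopaminergic cells 0.07 (0.985) and neuroblasts -0.02 (0.956), whose mean of 0.07 and test were upward. Adjusted over the list alone, Per1 and Bhlhb2 passed among clock genes and Dcx (0.72) among neuroblast markers, all named after their values were seen. Abundant members were Th at 202 ± 16.0 RPKM against 169 ± 12.9 in clean air, Syp at 520 ± 45.2 against 489 ± 15.5, and Mbp at 698 ± 76.9 against 653 ± 80.8. Gtl2, the 1 tested nuclear-retained RNA, had a log2 difference of -0.57 ± 0.21 (adjusted p = 0.818).

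By limma 18 of 12780 genes passed at 30 min, and all 18 had groups that did not overlap. A call itself favours separated groups, so this is no separate support. Of all tested genes 11.4% had groups that did not overlap, against 10% by chance. The median log2 difference of all tested genes was 0.08, and 756 genes had an unadjusted p under 0.05 against 639 for chance alone. With the mouse number as a block 22 genes passed, and 1396 had an unadjusted p under 0.05. That fit added Dusp5 (adjusted p = 0.0320), Mir132 (log2 1.59, 0.0246), Zfp652 (1.05, 0.0229), the unnamed ENSMUSG00000076004 (-1.57, 0.00489) and Gm23880 (-3.21, 0.0269), named after their values were seen, and it lost Cyr61 (0.0992). AK036329 overlaps Mapk4 (log2 0.03 ± 0.26) on the opposite strand, and without knowledge of the strand their reads cannot be assigned. Calls ended for Ier2 without clean air mouse 1 (adjusted p over its alternatives 0.00231 to 0.0611), for Nr4a1 without clean air mouse 1 or 2 or any 30 min mouse (6.83e-06 to 0.0952), for Egr3 without clean air mouse 2 or any 30 min mouse (0.00560 to 0.114) and for Dusp6 without clean air mouse 1 or 2 or any 30 min mouse (0.00632 to 0.159). They also ended for Cyr61 without any 1 of the 9 mice but 30 min mouse 2 (0.00231 to 0.281) and for AK036329 without any 1 clean air or 30 min mouse or 120 min mouse 3 (up to 0.171 with a mouse left out, 0.0135 to 0.414 over its alternatives), and the number of lists that passed fell from 5 to 3 without 30 min mouse 1.

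At 120 min, 9 genes were higher than in clean air and 2 lower. The largest rises among genes with a symbol were those of transcription factor genes: by the fit, Fosb rose 5.57-fold and Egr3 5.05-fold. Their mean levels were 27.0 ± 3.41 and 99.5 ± 10.4 RPKM, against 4.77 ± 2.33 and 20.1 ± 7.06 RPKM in clean air. Fosl2, another AP-1 subunit, rose 4.06-fold from 10.8 ± 5.07 to 42.6 ± 0.09 RPKM. Ccrn4l, which encodes nocturnin, and Bcor, which encodes a corepressor of the transcription factor BCL6, rose 2.30-fold and 2.29-fold, to 41.3 ± 4.66 and 14.6 ± 2.18 RPKM. Both genes that fell are short RNAs, the small nucleolar RNA Snord37 and Gm23880, annotated as a microRNA.

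Of the 28 immediate-early transcription factors, 6 were above clean air at 120 min, namely Fosb (2.48 ± 0.28), Egr3 (2.34 ± 0.24), Fosl2 (2.02 ± 0.25), Atf3 (1.92 ± 0.22), Nr4a3 (1.88 ± 0.22) and Nr4a2 (1.49 ± 0.18). Adjusted over the list alone 9 passed, with Fos, Klf10 (1.00) and Klf4 (0.75) added, the last pair named after their values were seen. The list rose with a median of 0.53 (adjusted p = 1.06e-11, but adjusted p = 0.0887 with an estimated correlation). The panel genes did not pass at 120 min. Fos had 20.8 ± 3.96 RPKM, 1.65 ± 0.33 above clean air on the log2 scale (adjusted p = 0.276). Egr1 had a log2 difference of 0.88 ± 0.35 (0.474), Nr4a1 of 0.81 ± 0.41 (0.567), Arc of 0.73 ± 0.29 (0.475), Bdnf of 0.53 ± 0.28 (0.590), Junb of 0.07 ± 0.22 (0.95) and Npas4 of -0.19 ± 0.20 (0.815). Clean air mouse 3 held 12.1 RPKM of Fos, 67.52 of Egr1 and 75.54 of Nr4a1, against 4.04 to 4.73, 21.24 to 22.29 and 18.12 to 22.94 RPKM in the other clean air mice. Without it Fos (2.11, adjusted p = 0.00341), Egr1 (1.42, 0.00341) and Nr4a1 (1.43, 0.0102) passed at 120 min, and over 24 alternatives their adjusted p ranged from 0.00341 to 0.703, 0.00341 to 0.750 and 0.0102 to 0.844.

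**Figure D2:**
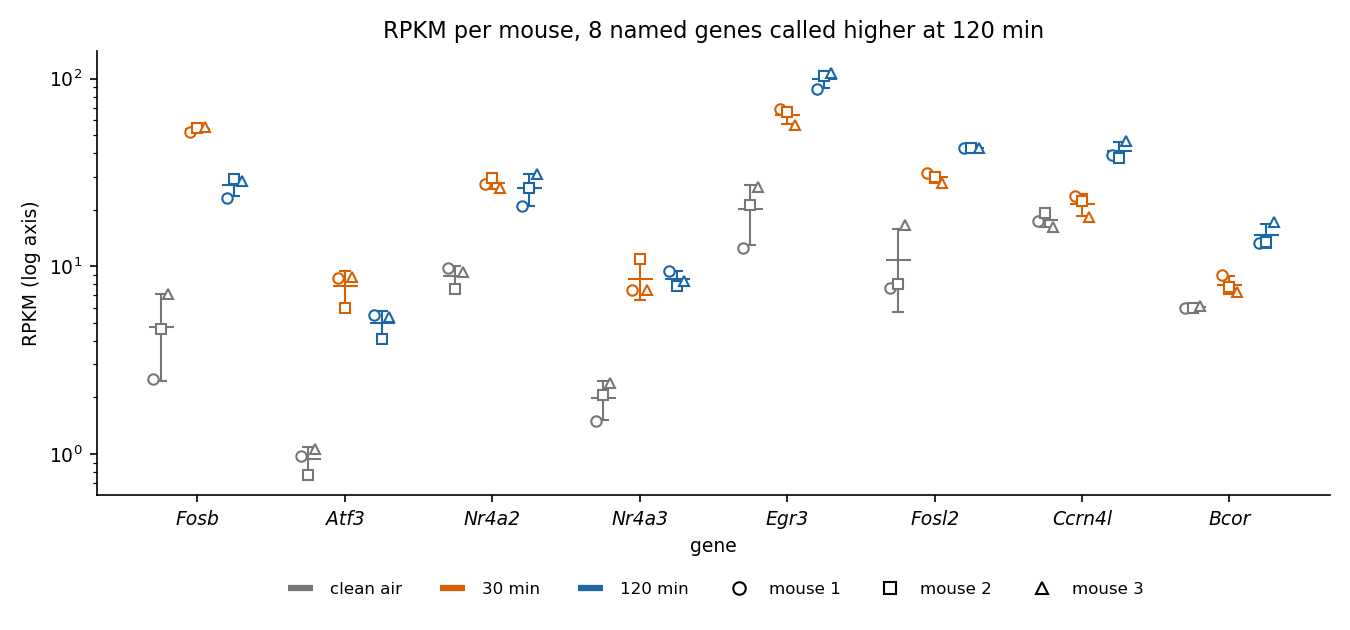
RPKM (log axis) of 8 genes called higher at 120 min in each of the 9 mice, by group, with points for mice, horizontal lines for group means and error bars of 1 SD. Egr3, Fosl2, Ccrn4l and Bcor had their highest means at 120 min, with 99.5, 42.6, 41.3 and 14.6 RPKM.

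None of the 25 activity-regulated effector genes was called at 120 min by limma genome-wide, and 3 passed when adjusted over the list alone. These were Homer1, the gene of a postsynaptic scaffold protein (1.63 ± 0.34, 32.9 ± 10.3 RPKM against 10.8 ± 4.62), Pcsk1, a prohormone convertase gene (1.01 ± 0.19), and Acan, the gene of an extracellular matrix proteoglycan (0.69 ± 0.18). The 3 were named after their values were seen, and their genome-wide adjusted p were 0.310, 0.182 and 0.339. In the fit with the mouse number as a block Homer1 passed genome-wide (adjusted p = 0.0252). The list rose with a median of 0.28 (adjusted p = 0.00271, but adjusted p = 0.0887 with an estimated correlation), while Vgf had -0.12 ± 0.21. Feedback regulators of MAP kinase signalling rose with a median of 0.41 (adjusted p = 0.000515, but adjusted p = 0.145 with an estimated correlation). No member was called genome-wide, and Spred2 (0.74 ± 0.20), Dusp6 (0.56) and Dusp5 (0.50 ± 0.16) passed when adjusted over the list alone.

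Glucocorticoid-responsive genes rose at 120 min with a median of 0.19 (adjusted p = 0.00851, but adjusted p = 0.478 with an estimated correlation). Of 18 tested, 17 were above clean air and none was called. Cdkn1a, a cell cycle inhibitor gene with 101 ± 4.62 RPKM against 59.2 ± 1.86 and named after its value was seen, passed when adjusted over the list alone. Mitral and tufted cell markers rose with a median of 0.35 (adjusted p = 0.0291, but adjusted p = 0.145 with an estimated correlation and 0.0579 in the fit with the mouse number as a block). Of these 8 markers none was called, Reln (0.90) and Tbx21 (0.51) passed when adjusted over the list alone and were named after their values were seen, and the abundant Doc2g and Slc17a7 had -0.27 ± 0.21 and -0.03 ± 0.21. Synaptic vesicle and postsynaptic genes rose with a median of 0.18 (adjusted p = 0.0336, but adjusted p = 0.145 with an estimated correlation), with 15 of 17 above clean air and none called, genome-wide or adjusted over the list alone. Vamp2 had 610 ± 23.8 RPKM against 483 ± 109, and Syp had 489 RPKM in both groups.

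The other 19 lists did not pass at 120 min and held no called gene. Their medians with adjusted p were 0.19 (0.213) for heat shock genes, -0.05 (0.334) for interferon-stimulated genes, 0.19 (0.334) for granule and other interneurons, 0.19 (0.334) for astrocytes, 0.14 (0.337) for clock genes and -0.08 (0.337) for olfactory ensheathing cells. Sex-chromosome genes had -0.24 (0.427), endothelial and mural cells 0.08 (0.575), mitochondrial genome genes 0.31 (0.581), neuroblasts 0.03 (0.621), dopaminergic cells -0.14 (0.751) and choroid plexus and meninges 0.15 (0.751). Microglia had 0.10 (0.835), olfactory sensory neurons -0.04 (0.873), frontal cortex neurons 0.11 (0.914) and red blood cells 0.21 (0.918). In 3 lists signs differed: oligodendrocytes had a median of 0.05 and a downward test (0.835), housekeeping genes a median of -0.02, a mean of 0.09 and an upward test (0.873), and neuropeptides a median of -0.02, a mean of 0.06 and an upward test (0.914).

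By limma 11 genes passed at 120 min, all with groups that did not overlap, which a call itself favours (13.1% of all tested genes, 10% by chance). An unadjusted p under 0.05 was found for 1223 genes. The gene ENSMUSG00000080509, which has no symbol, was listed at 0 in all 3 clean air mice and had 1.84, 2.26 and 5.08 RPKM at 120 min (log2 2.72 ± 0.40, adjusted p = 0.0368). With groups at or near 0 the size depends on the pseudocount, and with 0.1 and 1 in place of 0.5 it was 4.84 (adjusted p = 0.0160) and 1.94 (0.0873), in a range of 0.0160 to 0.179 over its alternatives. Snord37 had 9.53, 6.01 and 7.81 RPKM in clean air and 0, 1.38 and 0 at 120 min (log2 -3.39 ± 0.46, adjusted p = 0.0262). Gm23880 had 4.76, 11.26 and 6.69 RPKM in clean air and was listed at 0 in all 120 min mice (log2 -3.93 ± 0.54, adjusted p = 0.0262). With pseudocounts of 0.1 and 1 Snord37 had -4.98 and -2.70 and Gm23880 -6.17 and -3.03, and neither passed with 0.1 (0.146 each, in ranges of 0.00115 to 0.376 and 0.00506 to 0.419 over their alternatives). These short RNAs rest on 24 estimated reads in the clean air mice together and 1 in the 120 min mice. The count was 6 without clean air mouse 1, 3 without 120 min mouse 1 or 2, and 0 by limma without clean air mouse 2 or without 120 min mouse 3, where 1092 and 855 genes had an unadjusted p under 0.05. Each call thus ended (adjusted p up to 0.101 for Fosb, Egr3, Atf3, Nr4a3 and Nr4a2, 0.125 for Fosl2, 0.177 for Ccrn4l, Bcor and Snord37 and 0.179 for Gm23880 and ENSMUSG00000080509), those of Ccrn4l, Bcor, Snord37, Gm23880 and ENSMUSG00000080509 also without clean air mouse 3 (0.0789 to 0.139), of Bcor without 30 min mouse 2 or 3 (0.0634 and 0.0720), and of Snord37 and ENSMUSG00000080509 without 30 min mouse 3 (0.0580 and 0.0900), and the lists that passed numbered 3 instead of 6 without clean air mouse 1 or 120 min mouse 2.

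**Figure D3:**
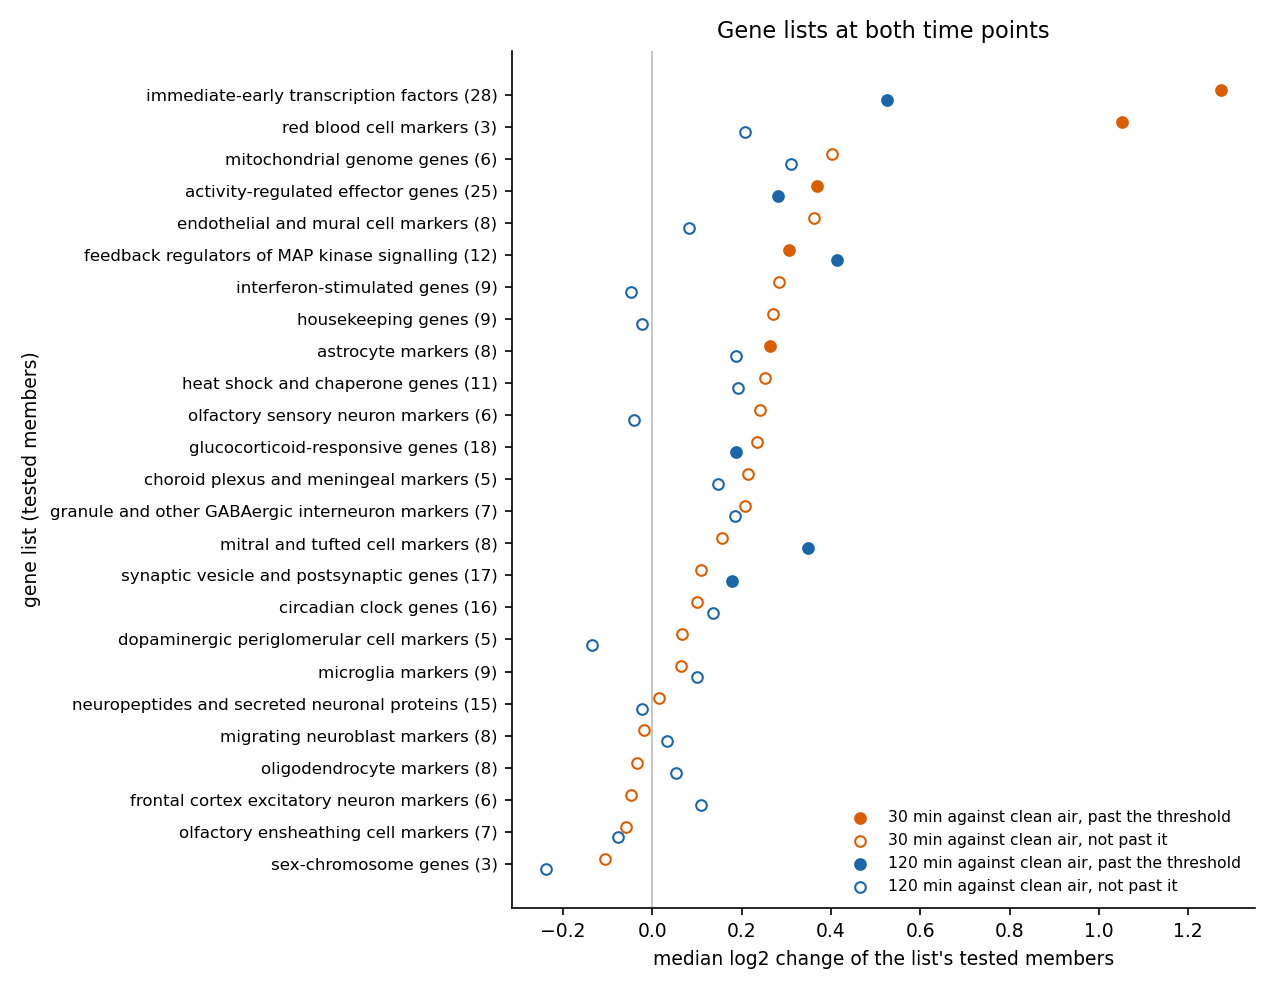
Median log2 change of each tested gene list at 30 min and at 120 min against clean air, with filled points for lists that passed camera and open points for the others. Immediate-early transcription factors had the largest median at both times, 1.27 and 0.53.

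Between 30 and 120 min, 10 genes fell and none rose by limma (176 higher at an unadjusted p under 0.05), and each of the 10 had risen at 30 min. Npas4 fell from 60.9 ± 6.42 to 6.07 ± 1.09 RPKM, near its clean air level of 7.01 ± 1.40 RPKM. Btg2 fell from 38.9 ± 4.95 to 5.84 ± 0.58 RPKM and Junb from 207 ± 30.7 to 33.3 ± 3.27 RPKM, beside 5.46 ± 0.60 and 32.6 ± 9.21 RPKM in clean air. Fos fell from a mean of 155 to 20.8 ± 3.96 RPKM and Arc from 285 ± 46.0 to 39.2 ± 4.28 RPKM. This contrast tests the difference between the time points itself.

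On the log2 scale the changes were -3.23 ± 0.20 for Npas4 (adjusted p = 6.25e-05), -2.88 ± 0.33 for Fos (0.00550), -2.84 ± 0.29 for Arc (0.00344), -2.63 ± 0.17 for Btg2 (6.25e-05) and -2.61 ± 0.22 for Junb (0.000695). They were -2.52 ± 0.37 for Cyr61 (0.0477), -2.50 ± 0.26 for Egr4 (0.00344), -2.47 ± 0.28 for Ier2 (0.00524), -2.37 ± 0.35 for Egr1 (0.0489) and -1.65 ± 0.18 for Dusp1 (0.00524). Of the 17 genes that rose at 30 min, these 10 fell, 5 were still called above clean air at 120 min (Fosb, Atf3, Nr4a2, Nr4a3 and Egr3), and 2 met neither criterion (Nr4a1 and Dusp6). The log2 difference from 30 to 120 min was -0.998 ± 0.281 for Fosb, -0.60 ± 0.22 for Atf3, -0.10 ± 0.18 for Nr4a2, 0.01 ± 0.22 for Nr4a3 and 0.63 ± 0.24 for Egr3, none of which passed (adjusted p = 0.999). Over the 17 genes a median of 27.1% of the log2 rise remained at 120 min. Bdnf had 0.27 ± 0.28 (0.999).

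Immediate-early transcription factors fell as a list from 30 to 120 min, with 7 of 28 called lower and 9 when adjusted over the list alone, Fosb and Nr4a1 added. The median was -0.33 (adjusted p = 8.16e-16, adjusted p = 0.0457 with an estimated correlation, and adjusted p = 0.142 with an estimated correlation in the fit with the mouse number as a block). Interferon-stimulated genes fell as a list with a median of -0.34 and 0 of 9 members above their 30 min level (adjusted p = 0.00119, but adjusted p = 0.448 with an estimated correlation). None was called by limma or when adjusted over the list alone, and the antiviral gene Ifitm3 and D12Ertd647e had -0.60 ± 0.36 and -0.34 ± 0.26. Red blood cell markers fell as a list with a median of -0.84 (adjusted p = 0.00697, but adjusted p = 0.448 with an estimated correlation), with none of 3 called and 1 when adjusted over the list alone, the heme synthesis gene Alas2 (-1.34, named after its value was seen). Mitral and tufted cell markers rose with a median of 0.08 (adjusted p = 0.0431, but adjusted p = 0.392 with an estimated correlation and 0.0701 in the fit with the mouse number as a block), with no member called. Among activity-regulated effector genes, which did not pass as a list (adjusted p = 0.357), Arc and Cyr61 fell. Adjusted over the list alone Homer1 (1.24 ± 0.34), Pcsk1 (0.59 ± 0.19) and Acan (0.52 ± 0.18) were higher at 120 than at 30 min, and Plk2 (-0.76), Snf1lk (-0.68) and Gadd45g (-0.66) were lower beside Arc and Cyr61, all 6 named after their values were seen. Feedback regulators of MAP kinase signalling did not pass (adjusted p = 0.351), with Dusp1 fallen and, adjusted over the list alone, Dusp6 lower and Spred2 higher. The other 19 lists had adjusted p of 0.275 to 0.994, and the neuropeptide, microglia and mitochondrial genome lists had medians of -0.02, -0.06 and -0.04, means of -0.02, -0.02 and -0.07, and upward tests. Of their members the clock gene Per2 (0.66, named after its value was seen) passed when adjusted over the list alone.

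By limma 10 of 12780 genes passed between 30 and 120 min, all with groups that did not overlap, which a call itself favours (10.6% of all tested genes, 10% by chance). An unadjusted p under 0.05 was found for 430 genes against 639 for chance alone. In the fit with the mouse number as a block it was found for 854, so the count under that of chance depends on the block. The call of Ier2 ended without 120 min mouse 3 (adjusted p over its alternatives 0.00153 to 0.0505), that of Cyr61 without any 1 mouse but 30 min mouse 2 (0.00229 to 0.314), and that of Egr1 without any 1 mouse but clean air mouse 3 (8.43e-05 to 0.314). Nr4a1, with -2.18 ± 0.41, did not pass (adjusted p = 0.244) but passed without clean air mouse 3 (1.16e-04), in a range of 1.16e-04 to 1 over its alternatives, and the lists that passed fell from 4 to 2 without 30 min mouse 1 and to 1 without 120 min mouse 1.

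The same 5 genes, Fosb, Atf3, Nr4a2, Nr4a3 and Egr3, were called higher than clean air at both times, and no gene was called lower at both. They encode a subunit of AP-1, a stress-responsive factor, a pair of orphan nuclear receptors and a zinc finger factor. Both comparisons use the same 3 clean air mice, so their chance values are shared. In 50 simulations of unchanged groups against shared controls the mean and the highest number of shared rises were 0, which unchanged groups give for lack of calls and which is no test of sharing. By comparison, independent lists of the observed sizes would share 0.0120 genes upward and 1.56e-04 downward. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.63 (0.50 in the simulations, at most 0.53), with a covariance of 0.0735 against a simulated 0.0407, a difference of 0.0327. The share of genes with the same sign was 73.6% against 66.7%. Part of the excess of shared calls may come from the shared controls, since 3 clean air mice are too few to divide between the comparisons. The simulated r, covariance and share of the same sign hold the controls' part only for noise independent across genes and equal in all libraries. Array weights, which are lower for libraries with more spread, were 1.14, 0.60 and 0.46 in clean air mice 1 to 3. They were 0.88 to 2.32 in the exposed mice, so the excess over the simulations may also come in part from the shared controls. The overlap was 0 without clean air mouse 2 or without 120 min mouse 3, where limma called no gene at 120 min (1092 and 855 genes at an unadjusted p under 0.05), 3 and 2 without 120 min mice 1 and 2, and 10 without clean air mouse 3.

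**Figure D4:**
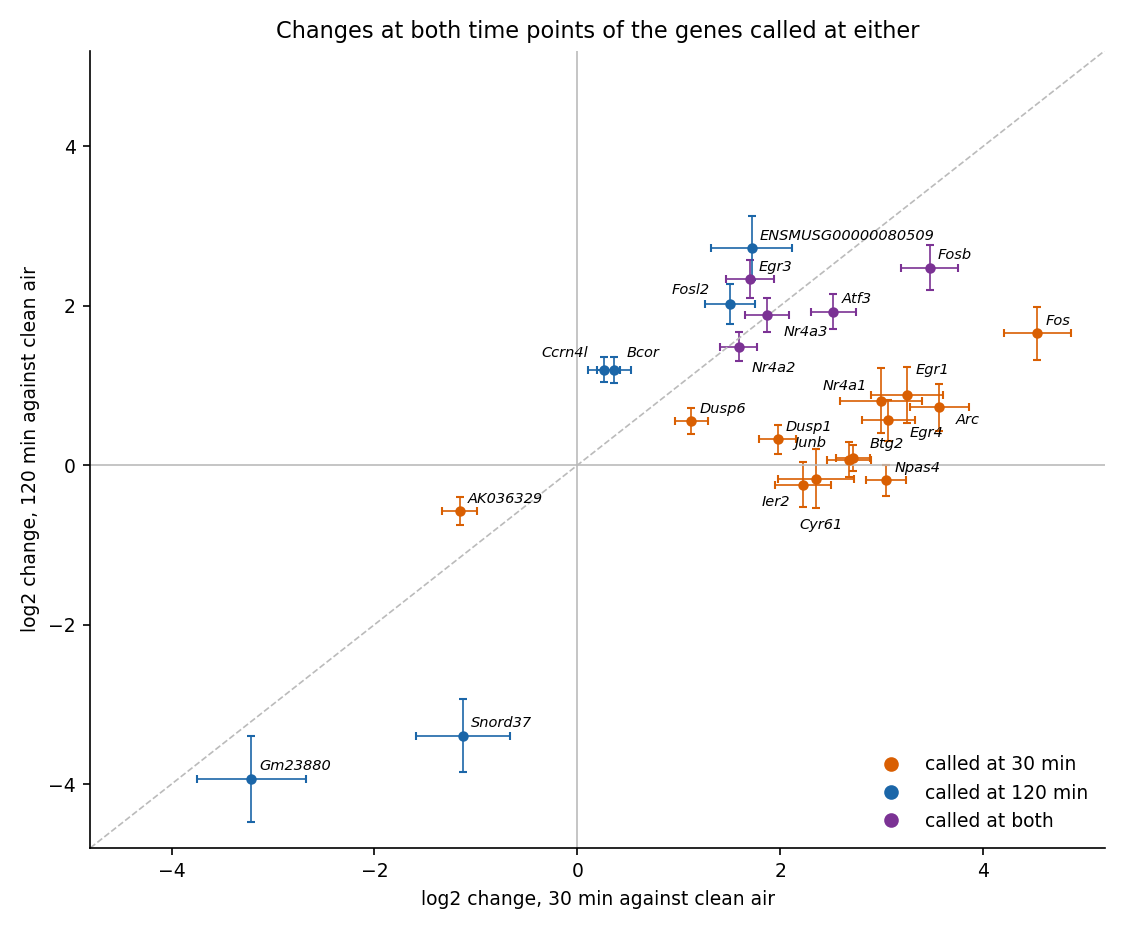
Log2 change at 120 min against log2 change at 30 min, both against clean air, for the genes called at 1 or both times, with error bars of 1 SE, colors for the time of the call and a dashed line of equal change. Fosb, Atf3, Nr4a2, Nr4a3 and Egr3 were called at both times, and Fos, Arc and Npas4 had changes of 4.53, 3.57 and 3.04 at 30 min beside 1.65, 0.73 and -0.19 at 120 min.

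Averaged over both exposed groups, 16 genes passed, 15 higher and 1 lower than in clean air. The largest rises were those of Fos (3.09 ± 0.29), Fosb (2.98 ± 0.24), Atf3 (2.22 ± 0.19), ENSMUSG00000080509 (2.22 ± 0.34), Arc (2.15 ± 0.25), Egr1 (2.07 ± 0.31) and Egr3 (2.02 ± 0.21), and the gene that fell was Gm23880 (-3.57 ± 0.47), with sizes that depend on the pseudocount for it and for ENSMUSG00000080509. With the mouse number as a block 20 genes passed, with Dusp6, Slc16a11, Mir132, Zfp652 and ENSMUSG00000076004 added, named after their values were seen, and ENSMUSG00000080509 lost (adjusted p = 0.0716). The others were Nr4a3, Egr4, Fosl2, Nr4a2, Npas4, Btg2, Junb and Dusp1. Without clean air mouse 2 the count was 9. The F test over the 3 groups called 21 genes, which added Nr4a1, Ccrn4l, Cyr61, Bcor, Ier2 and Snord37 to those of the average and left out ENSMUSG00000080509.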

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

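The tests of sequencing depth, of counting noise and of a mislabelled mouse, with the numbers of genes used, and those of the mouse number beyond the block, were chosen after the results they concern had been seen. The difference between the time points itself was tested for every gene, and 10 genes differed. All 10 had risen by 30 min and were lower at 120 than at 30 min, with log2 changes of -3.23 for Npas4, -2.88 for Fos, -2.84 for Arc, -2.63 for Btg2, -2.61 for Junb, -2.52 for Cyr61, -2.50 for Egr4, -2.47 for Ier2, -2.37 for Egr1 and -1.65 for Dusp1. Groups of 3 mice were not tested for outlying samples.

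Regrouping the libraries gave fewer calls in the comparisons of 2 groups. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes in each comparison. The real counts were 18, 11 and 10 genes at 30 min, at 120 min and between the times, and the highest of the other splits gave 1, 2 and 3. With 10 splits the share is never under 0.1, too few for a share under 0.05. For 30 min against clean air, 4 splits part all 3 pairs of the same mouse number, of which the other 3 called 0 genes by limma (155 to 420 at an unadjusted p under 0.05, against 756 in the real split). The 6 that part fewer called at most 1, with 556 to 1448 genes at an unadjusted p under 0.05, so that some exceeded the real split by that count. For the average of both exposed groups 4 of 100 drawn splits of the 9 libraries gave as many as the real 16 genes (highest other 53). For the F test 2 of 100 gave as many as the real 21 (highest other 114), the real split included in both. Both shares were under 0.05, but 100 draws place a share of 4 of 100 only roughly. The draws also did not keep to the mouse number, so they cannot exclude chance. The splits with more calls by the average, 53, 49 and 34, set the mice numbered 1, 2 and 1 apart from the rest, and 114 comes from the split by mouse number, which points to a structure of the samples. With the mouse number as a block the average called 20 genes.

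Libraries with the same mouse number deviated together from their group means, with a mean correlation of 0.265 across genes, which are not independent replicates, and all 9 libraries correlated best with one of their own number. The tables argue against reads of genes with near-identical copies, since the mean correlation was 0.264 on genes that share no 32-mer with another gene, and against GC content or transcript length as the whole cause, since it was 0.220 after those trends were taken out (0.266 before). A difference in sequencing depth stays open: the first component of the deviations (32.6% of their variance) had r = 0.742 with log2 depth over the 9 libraries (exact permutation p = 0.0787 over 216 arrangements, rho = 0.783 with p = 0.0556, r = 0.604 without the 2 farthest libraries). Taking the depth trend out lowered the mean correlation to 0.0317, and in numbers 1 and 2, all shallower and all deeper than their group means, depth and number cannot be told apart. In number 3 they part, with log2 depth deviations of 0.646 in clean air and -0.739 at 120 min for libraries that had r = 0.0897 with each other, near the highest of 0.0865 between different numbers, and a preparation batch or litter was not tested because the labels give none.

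The short RNAs Snord37 and Gm23880 were called lower at 120 min on 14 and 10 estimated reads in clean air against 1 and 0. The tables argue against reads of the surrounding gene, since Eef2 and Ep300 had log2 changes of 0.16 ± 0.22 and 0.50 ± 0.16. The bound set in advance was a change under 0.5, which 0.503 for Ep300 missed, and the reading rests on a fall of 1 lying outside both intervals, a criterion added afterwards. Counting noise of few reads stays open: in 0.508 of 10000 simulated splits of the reads of all 147 tested RNAs of up to 150 nt the smallest p was at least as small as that of the called RNAs (0.0111), and 11 of the 147 had a p that small, down to 4.24e-94. A first version of this test pooled only the called RNAs (24 reads against 1, exact binomial p = 0.000103) and was replaced because those had been chosen for being low.

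Clean air mouse 3 had higher levels of the 17 genes that rose at 30 min than the other clean air mice, with a median log2 difference of 0.50 (SD 0.57 over genes), its value the highest of the clean air group in 14 of 17, and none of 10000 expression-matched lists as high. The lists were drawn gene by gene, while the 17 genes may move together within a mouse. The share of lists may therefore overstate how unusual this mouse is. The tables argue against a mislabelled mouse of the 30 min group: on the 15 to 18 genes called higher at 30 min in fits without this mouse, with every 30 min mouse or 1 of them left out, its median change was at most 26.6% of that of the 30 min mice used, against 95.6% to 104% for the mouse left out. They argue against a mislabelled mouse of the 120 min group as well: on the 5 to 9 genes called higher at 120 min in such fits its median was at most 43.8%, against 94.2% to 107%, and it lay below every 120 min mouse in 7 of the 9, though above every one in Egr1 and Nr4a1. They also argue against scaling of the library, since the median was 0.61 after median ratio scaling, while earlier activity, handling and time of collection were not tested and stay open. The tests of the label replace 2 earlier versions whose values had been seen: the first used the 17 genes, chosen with this mouse in the clean air group (44.8% at 120 min), and the second the 10, 20 or 50 genes with the smallest p, where 120 min gave up to 48.8% with 20 and 60.3% with 50, past the bound of 50%, and was replaced because most of the 50 were not called at 120 min.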

How the results depend on the processing

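Array weights, voom weights, depth as a covariate and the leaving out of genes without a symbol in the table were chosen after seeing the data. Over 26 settings, 186 named gene results had 4452 alternative values. Of these, 4116 had the same direction and side of the threshold, 162 were no longer past it and 6 were newly past it. Another 168, past the threshold in neither fit, had the opposite sign, and 0 of those past it in either fit were reversed. Only 38 of the 186 results were past the threshold in the main fit, and all 162 losses fell on these 38. Losses went from 0 of 24 alternatives for Fos at 30 min up to 16 of 24 for Cyr61 at 30 min. Median ratio scaling shared 15 of 18, 11 of 11 and 9 of 10 calls at 30 min, at 120 min and between them, and quantile normalization shared 16, 10 and 8. Genes changed at 120 min numbered 2 with only the 2 groups compared, 7 with array weights, 5 with log2 depth as a covariate and 0 to 11 with each library left out. The overlap of both times was 0 with only the 2 groups compared and 0 to 10 with each library left out, and the average over both times had 9 to 18 with each library left out and 14 to 20 in the other settings. Fewer samples give fewer degrees of freedom; the cause was not tested otherwise. Lists changed at 30 min numbered 2 by camera with an estimated correlation, 3 by fry, 3 with array weights and 3 to 6 with each library left out. At 120 min they numbered 0 by camera with an estimated correlation (5 at an unadjusted p under 0.05, and 5 by fry) and 3 to 8 with each library left out. Between the times they numbered 1 by camera with an estimated correlation, 1 by fry, 2 with a mean of at least 3 RPKM and 1 to 5 with each library left out. The calls that hold with an estimated correlation are those of immediate-early transcription factors at 30 min and between the times and of activity-regulated effector genes at 30 min. With the mouse number as a block as well, immediate-early transcription factors at 30 min hold (adjusted p = 0.0234), and they between the times (0.142) and effector genes at 30 min (0.102) do not. Nr4a1 between 30 and 120 min also passed with only the 2 groups compared (adjusted p = 2.66e-04) and with array weights (0.0141), in a range of 1.16e-04 to 1. All 9 libraries correlated best with their own number. In the comparisons with 120 min a same-number pair fell under the criterion of 0.1 (lowest r 0.0897 with clean air and 0.0810 with 30 min). Numbers were therefore not treated as pairing there, which does not show that the mice were unpaired. The block raised the genes at an unadjusted p under 0.05 from 1223 to 1910 at 120 min and from 430 to 854 between the times. At 120 min it added Homer1 (0.0252) and Agbl3 (0.0465) and lost Snord37 and ENSMUSG00000080509 (0.0718 each). It also ended the list call of mitral and tufted cell markers there (0.0579). Between the times it added Agbl3 (0.0372), lost Cyr61 (0.120) and ended the mitral and tufted call (0.0701). Beside these and the changes at 30 min and in the average given with those results, the block changed no other gene call of those comparisons. Voom for lists, a 2-fold minimum for lists and the F test, and the 2-group fit for the F test and the average were not run. Depth limits values near 0.104 to 0.434 RPKM for a transcript of 1 kb.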

Other observations

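Every test in this part was run on patterns of the same data, and the tests of mouse number and of single clock genes were chosen after the results had been seen. Among 16 tested circadian clock genes none was called genome-wide by limma at 120 min, while 4 passed when adjusted over the list alone. Clock (0.78 ± 0.19), Per2 (0.60 ± 0.17) and Npas2 (0.51 ± 0.16), which encode core regulators of the clock, were higher than in clean air, and Dbp (-0.77 ± 0.18), a clock output gene, was lower, with 50.2 ± 8.39 RPKM against 85.2 ± 3.51 RPKM (n = 3). The list, with members that went both ways, did not pass camera (adjusted p = 0.337), while fry's mixed test gave an adjusted p of 7.94e-06 at 120 min, 0.00694 at 30 min and 0.000286 between the times. Fry's mixed test passed at 120 min for other lists too, among them glucocorticoid-responsive genes (adjusted p = 0.0240) and mitral and tufted cell markers (0.000397). Per1 and Bhlhb2, the clock genes that passed over the list alone at 30 min, also stand on the list of immediate-early transcription factors. Per1, which neuronal activity also induces, had 32.9 RPKM in clean air, 55.5 RPKM at 30 min and 45.6 RPKM at 120 min. The hour at which each mouse was taken is not given in the sources used here.

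Mice with the same number shared levels of mitochondrial and other genes. An F test for number with the group in the model called 88 genes by limma. The mitochondrial gene mt-Nd6, a subunit of respiratory complex I, had means of 99.5, 669 and 271 RPKM in mice numbered 1, 2 and 3 (adjusted p = 0.00144), and Gtf2h5, a subunit of transcription factor TFIIH, had 63.9, 12.7 and 17.1 RPKM (0.00598). Tmsb4x, a thymosin gene that binds actin, had 67.0, 192 and 48.2 RPKM. Mitochondrial genome genes had a median log2 difference from the other numbers of 1.48 in number 2 (adjusted p = 1.59e-06, but adjusted p = 0.927 with an estimated correlation), -1.03 in number 1 (2.73e-06, but adjusted p = 0.978 with an estimated correlation) and -0.42 in number 3 (0.0479, but adjusted p = 0.962 with an estimated correlation). Neuropeptides and secreted neuronal proteins had -0.19 in number 1 (adjusted p = 0.0105, but adjusted p = 0.978 with an estimated correlation) and 0.35 in number 2 (adjusted p = 0.00883, but adjusted p = 0.927 with an estimated correlation). In number 3, which includes clean air mouse 3, immediate-early transcription factors had 0.21 and granule and other GABAergic interneuron markers -0.29 (adjusted p = 0.0211 each, but adjusted p = 0.962 each with an estimated correlation).

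A hypothesis was that genes that rose within 30 min are short, because a short primary transcript may be completed within the exposure. The 17 genes had a median genomic span of 5162 bp against 23271 bp in 10000 expression-matched random lists and 24702 bp over all tested genes. The share of lists as short was 1e-04, the smallest these permutations can give. Of the genes called higher at 120 min and not at 30 min, Fosl2, Ccrn4l and Bcor span 22042, 27198 and 123616 bp. Fosl2 already had a log2 change of 1.51 at 30 min (limma adjusted p = 0.0619). Among the 17 genes Dusp1, Atf3 and Nr4a3 span 56539, 47744 and 41295 bp, so the spans of earlier and later genes overlapped. Short spans are also known of immediate-early genes as a class, so the test does not separate transcription time from membership of that class.

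A second hypothesis was that the genes fell back between 30 and 120 min to the degree that their 3′ UTRs hold ATTTA, a pentamer found in unstable transcripts, which could shorten their life. Across the 17 genes, which are not independent replicates, the number of pentamers had rho = 0.25 with the log2 change from 30 to 120 min (permutation p = 0.322), r = 0.39 (permutation p = 0.118) and r = 0.09 without the 2 farthest genes. The sign was opposite to that hypothesis but is not established, since neither correlation passed. More pentamers did not go with a larger fall among these 17 genes. The fall was not scaled by the rise at 30 min, which went from 1.12 for Dusp6 to 4.53 for Fos on the log2 scale. The test therefore cannot decide whether the pentamers were a source of the differences. The life of the transcripts was not measured, and the pentamers were not scaled by UTR length.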
